A study of Mus musculus with 24 samples.

How the data were processed

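Liver RNA from 24 female mice was measured by real-time PCR on a 96-well plate of glucose metabolism genes. The plate holds 84 genes of interest, 5 housekeeping genes and 7 control wells. The control wells are 1 for genomic DNA, 3 for reverse transcription and 3 for a positive PCR control. The series title speaks of fatty acid metabolism with the word glucose in brackets, and the header of the raw table names an array for PPAR activation. None of the fatty acid gene lists fixed beforehand has a gene on this plate, and the Ppara gene has no well, so the deletion itself could not be checked.

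Per the labels' protocols, RNA was isolated with an RNeasy kit and reverse transcribed with a kit of the array's supplier, and the wells were read with SYBR Green. Instrument, threshold setting and analysis software are not given in the sources used here. The first deposited table holds raw threshold cycles (Ct) per well and animal, a value in PCR cycles in which 1 cycle less stands for about 2 times more template. The second deposited table holds the mean Ct of each group. Recomputed group means matched it within 0.00497 cycles once every Ct above 35 and every empty value was set to 35, so the authors applied that ceiling. The third deposited table holds the difference between each gene's mean Ct and that of B2m, which is a log2 scale with the sign turned, so B2m alone was the authors' reference gene. The fourth holds these values as a ratio to B2m, 2 to the power of the negative difference, and the fifth, per the file headers, holds fold changes between group means. The last deposited table gives fold regulation, in which a fold below 1 is written as its negative inverse. Its values were recovered from the raw table within 6.81e-05 on the log2 scale. In the table of mean Ct, 4 of the 5 housekeeping genes stand at other positions than in the raw table, while their values match by gene.

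The columns of the raw table name the group of each animal, a prefix (A, A2, B or B2) and in some cases a colour, but no replicate number. Animals are therefore named by group, prefix and colour, with "none" where no colour is given, and were not tied to single sample records. The labels speak of 6 mice per group, so each column was taken as 1 animal. No 2 columns were duplicates, since the smallest SD of the Ct difference between any 2 animals was 0.401 cycles over the genes.

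Values for the tests were −(Ct − Ct of B2m) per animal, written −ΔCt, with the same ceiling of 35. Genes with a Ct under 35 in at least 6 animals were tested, which left 81 genes of interest. The other 3 wells, among them those annotated Ogdh and Pgk2, were not tested, because none of the 24 animals had a value under 35. A linear model with 4 group means and a shared spread (20 residual degrees of freedom) was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no trend, not robust). P-values are two-sided and were adjusted by Benjamini-Hochberg within each comparison, with a threshold of 0.05. Errors of log2 fold changes are standard errors of this model. The test, the filter, the ceiling, the gene lists and most alternatives were fixed before the data were examined. The written design did not say whether housekeeping genes belong among the tested genes. They were left out only after a first fit with all 86 genes past the filter, B2m itself included, had been seen. That first fit called 1 gene for 2,4-DNT in wild-type mice, 11 genes (10 higher, 1 lower) for the genotype on vehicle and 1 gene for the genotype on 2,4-DNT.

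Gene lists (pathways, liver-type isozymes, isozymes of other tissues and testis isozymes) were tested with fry of limma where at least 3 members were tested, which gave 10 lists. Its directional p asks whether the members move one way on balance, and its mixed p whether they change in either direction. Neither sets a list against other genes. Among the known PPARα targets listed beforehand only 2, Pdk4 and Gys2, are on the plate, so that list was not tested. The genes named in each comparison are up to 12 per direction with the largest change among those past the threshold, together with the preset genes Pdk4, Pck1, G6pc, Fbp1, Pklr, Gys2, Acly and G6pdx and the housekeeping genes. Some genes are not reported here by name. Other names are marked as chosen after their values were seen. Symbols are those of the files. All 89 named wells matched the mouse RefSeq gene table (GRCm38.p6) by accession, 87 with the same symbol, and Pgm1 and Pgm2 are exchanged between the sources. No coordinates were used.

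The fit was tested on simulated data made with the spread of the 81 genes, in which 20 genes were changed in each of 100 simulations. For 2,4-DNT in wild-type mice, 43.2% of the genes changed by a log2 fold of 0.5 were recovered, 84.6% of those changed by 1 and 97.9% of those changed by 2, and 3.29% of the calls were false. For the difference of the 2,4-DNT effect between genotypes the recovered shares were 16.7%, 66.5% and 94.2%. These shares hold for 20 changed genes of 81. Fewer changed genes were not simulated, and the recovered share can then be lower, because the adjustment is stricter.

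The alternatives were other references (the median of the genes, each other housekeeping gene, the mean of all 5), a ceiling of 40, late values as missing, no filter, a filter at a mean Ct of 30, a trended robust spread, only the groups compared, exact permutation per gene, an added fold minimum of 1.5, and each animal left out. Lists were also tested with the median reference, by permutation and with camera using an estimated correlation. Added after seeing the data were the prefix as a block, the colour as a block, the fit without 2 doubted animals, the gluconeogenesis list without the wild-type 2,4-DNT animal A red, and the housekeeping genes tested with the others. The 2 doubted animals were the wild-type vehicle animal B blue and the wild-type 2,4-DNT animal B2 blue. Figures were drawn with matplotlib 3.10.9. Real-time PCR gives no read depth. The precision is set by 6 animals per group and by the ceiling, which 53 empty values and 25 later values of the 2016 values of the genes of interest reached.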

Results

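The study asked how the liver responds to 2,4-dinitrotoluene (2,4-DNT), a nitroaromatic compound used in making explosives and polyurethane, and whether the response depends on PPARα, a nuclear receptor that controls genes of lipid use. Wild-type C57Bl/6N mice and mice lacking PPARα received 134 mg/kg of 2,4-DNT per day, or vehicle, by oral gavage for 14 days. The source label of all 24 samples also names an endurance swim, which the protocols do not describe. The 4 groups held 6 female mice each, and liver RNA of each mouse was read on 1 plate of glucose metabolism genes. Between 78 and 81 of the 84 genes of interest had a Ct under 35 in each animal. The positive PCR control was even, with means of 18.7 to 18.9 cycles per animal. The reverse transcription control lay between 21.7 and 22.6 cycles in 23 animals and at 18.6 in the wild-type 2,4-DNT animal B2 blue. Among the 23 it was latest in the wild-type vehicle animals B blue and B none, at 22.6 and 22.1 cycles. The genomic DNA control was empty in 9 animals and never earlier than 36.0 cycles in the others.

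Levels followed the tissue for which the annotated isozymes are typical in part of the plate only. The earliest well was annotated Bpgm, an enzyme typical of red blood cells, at a mean Ct of 18.4 over the 24 animals. The wells annotated Gys2 (liver glycogen synthase) and Pfkl (liver phosphofructokinase) came up late, at 29.1 and 31.3 cycles. G6pc, the glucose-6-phosphatase that releases glucose from the liver, and Fbp1, the fructose bisphosphatase of gluconeogenesis, lay at 34.0 and 34.6, next to the ceiling. Ogdh, a subunit of a citric acid cycle enzyme present in nearly all cells, was not detected in any of the 24 animals. In contrast, Mdh1b and Aldoc, the brain-type aldolase, which are not typical of hepatocytes, lay at 23.5 and 22.9 cycles. Other wells went the expected way. Pygl (liver glycogen phosphorylase), Pklr and Pck1 were early, at 21.5, 21.7 and 22.2 cycles, Pgam2, Phkg1 and Prps1l1 were late, at 31.1, 33.1 and 33.2, and Pgk2 had no value under 35. The 10 wells annotated as liver-type isozymes had a mean Ct of 28.6, and the 16 annotated as isozymes of other tissues or testis 27.3, a difference of −1.26 cycles (other minus liver). It was −6.16 in plate rows A to D and 6.53 in rows E to G. Over the whole plate the difference was −1.10 in wild-type vehicle animals, −1.39 in wild-type 2,4-DNT animals, −1.24 in PPARα-null vehicle animals and −1.32 in PPARα-null 2,4-DNT animals. Comparing wells assumes similar PCR efficiency. Bpgm, Ogdh, Pfkl, Mdh1b, Aldoc, Pygl, Pgam2, Phkg1, Prps1l1 and Pgk2 were singled out after their values were seen. All gene names below are the names the files give to the wells.

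**Figure D1:**
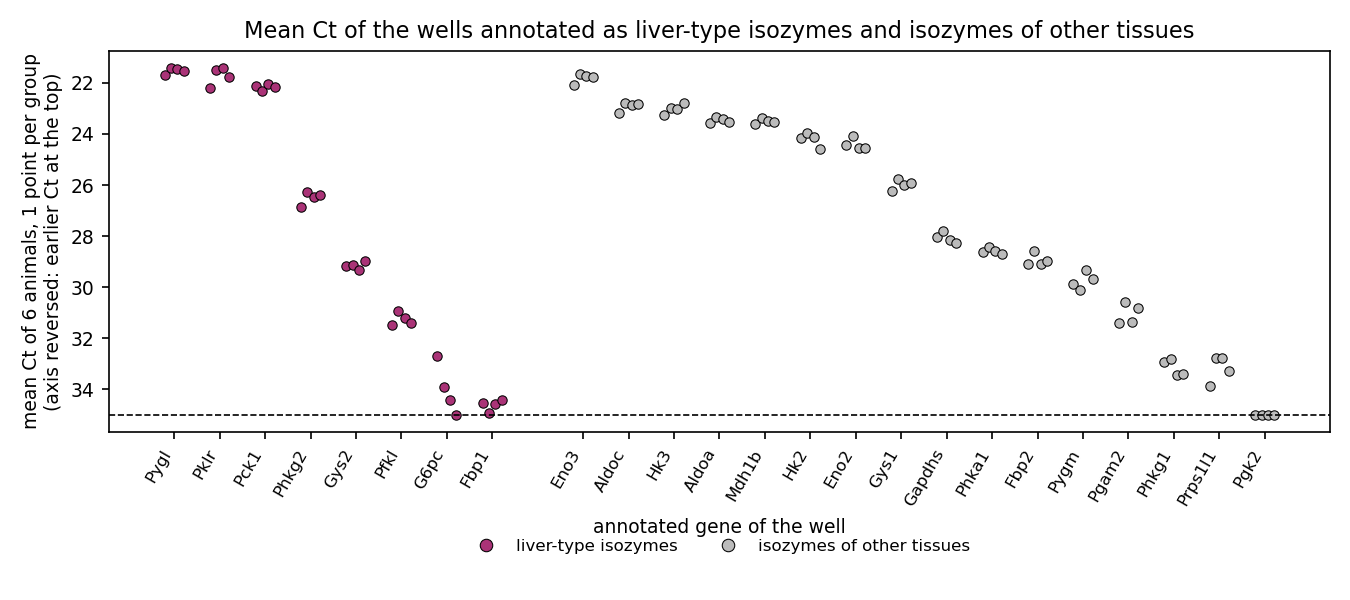
Mean Ct (vertical axis, in cycles, reversed so that earlier wells stand higher) of 8 of the 10 wells annotated as liver-type isozymes (purple) and of the 16 annotated as isozymes of other tissues or testis (grey), with 1 point per group of 6 animals in the order wild-type vehicle, wild-type 2,4-DNT, PPARα-null vehicle, PPARα-null 2,4-DNT, and the ceiling of 35 as a dashed line. Gys2, Pfkl, G6pc and Fbp1 lie at 29.1 cycles or later and Mdh1b and Aldoc at 23.5 and 22.9, while Pygl and Pklr lie at 21.5 and 21.7 and Phkg1 at 33.1.

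The first comparison asked what 2,4-DNT changed in wild-type liver. Of 81 genes tested, 2 fell and none rose. Pdpr, the regulatory subunit of pyruvate dehydrogenase phosphatase, fell from a −ΔCt of −1.33 ± 0.99 (SD, n = 6) to −2.92 ± 0.21 (SD, n = 6), a log2 fold change of −1.59 ± 0.35 (SE), or 0.332-fold (limma, adjusted p = 0.0124). G6pdx, the first enzyme of the oxidative pentose phosphate pathway, fell from 2.98 ± 0.54 to 1.75 ± 0.11 (SD, n = 6), a log2 fold change of −1.23 ± 0.33 (SE), or 0.426-fold (adjusted p = 0.0453). For both genes all 6 treated animals lay below all 6 vehicle animals, which chance gives for 0.216% of genes in either direction, or 0.175 genes of 81.

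**Figure D2:**
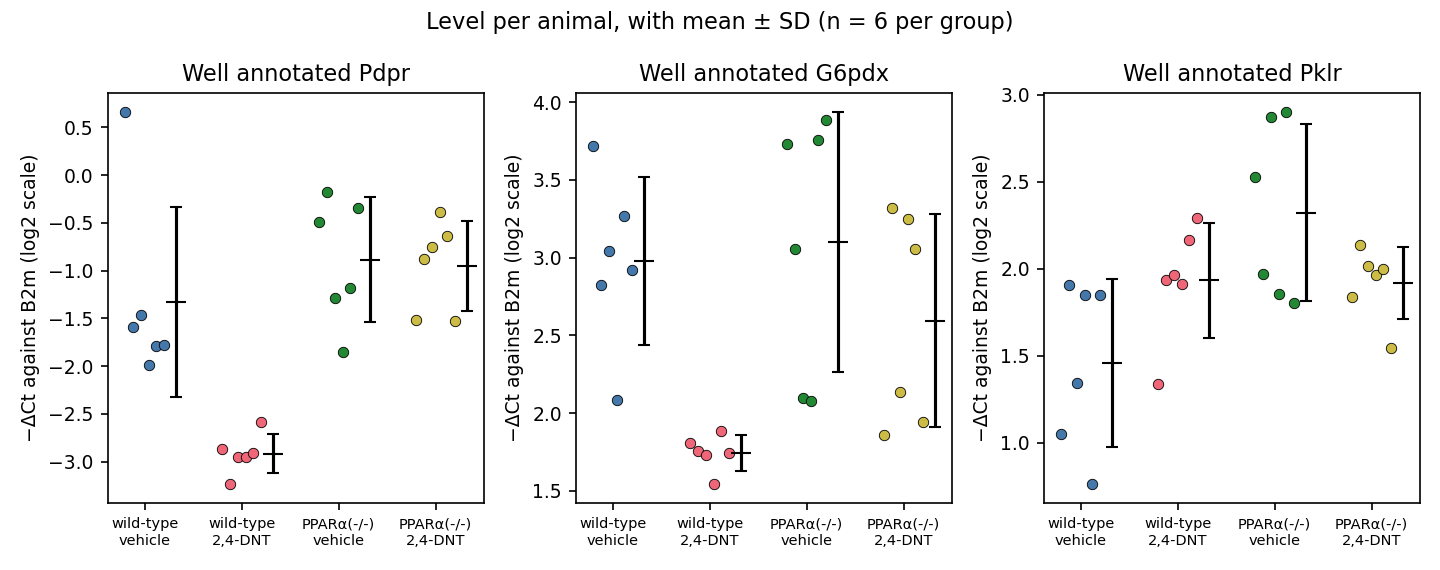
Level per animal as −ΔCt against B2m (vertical axis, log2 scale, higher is more RNA) in the wells annotated Pdpr, G6pdx and Pklr, with 1 point per animal and the mean ± SD of the 6 animals beside each of the 4 groups. Wild-type 2,4-DNT animals average −2.92 for Pdpr and 1.75 for G6pdx, below wild-type vehicle animals at −1.33 and 2.98, and Pklr averages 1.46 in wild-type and 2.32 in PPARα-null vehicle animals.

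None of the preset liver genes other than G6pdx passed the threshold with 2,4-DNT in wild-type mice. G6pc had a log2 fold change of −1.43 ± 0.52 (SE, adjusted p = 0.300), with a value under the ceiling in 5 vehicle and 4 treated animals, and Fbp1 −0.60 ± 0.28 (adjusted p = 0.417), with 4 and 1 such animals. Pck1, the enzyme that commits oxaloacetate to gluconeogenesis, differed by −0.39 ± 0.37 (adjusted p = 0.758), or by 0.13 ± 0.15 without the 2,4-DNT animal A red, Gys2 by −0.19 ± 0.21 and Acly, the source of cytosolic acetyl-CoA, by −0.02 ± 0.21. Pdk4, a kinase that switches off pyruvate dehydrogenase and a PPARα target, differed by 0.26 ± 0.19 (adjusted p = 0.719), and Pklr, the liver pyruvate kinase, by 0.47 ± 0.23 (adjusted p = 0.417). In the gluconeogenesis list 6 of 7 members had a negative value (mean log2 fold change −0.51), and the directional test gave an adjusted p of 0.177. Without the 2,4-DNT animal A red 5 of 7 were negative (adjusted p = 0.766). The adjusted p was 0.214 with the prefix as a block, 0.368 with exact permutation, 0.377 with the median of the genes as the reference and 0.0350 with camera and an estimated correlation, which sets the list against the other genes. The other 9 lists gave adjusted p values of 0.660 or more. The pyruvate dehydrogenase and pentose phosphate lists each held 1 lower gene, and also 1 when adjusted over the list alone, and the other lists held 0 by either count. The Pdpr call ended with exact permutation (adjusted p = 0.0877, the lowest that 2 tied genes can reach) and with the colour of the column as a block (log2 fold change −1.50 ± 0.38, adjusted p = 0.0620). The G6pdx call ended in both settings, with the prefix as a block, with a ceiling of 40, with 3 of 6 other references, without both doubted animals (log2 fold change −1.08 ± 0.36, adjusted p = 0.274) and in 13 of 24 fits that left out 1 animal. Its log2 fold change lay between −1.74 and −1.20 under the other references and was −1.19 ± 0.34 with the colour as a block. The mean difference of Pdpr within prefixes A, A2, B and B2 was −1.24, −1.36, −2.18 and −1.28, and that of G6pdx −0.33, −1.28, −1.68 and −1.21, from 1 or 2 animals per group each.

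The second comparison asked the same in mice without PPARα. No gene passed the threshold (limma, lowest adjusted p = 0.560). At an unadjusted p under 0.05 there were 5 genes, 1 higher and 4 lower, and the exact permutation test called 0. Pdpr was at −0.89 ± 0.66 (SD, n = 6) on vehicle and at −0.95 ± 0.47 (SD, n = 6) on 2,4-DNT, and G6pdx at 3.10 ± 0.84 and 2.59 ± 0.69, a log2 fold change of −0.51 ± 0.33 (SE, adjusted p = 0.709). Pklr differed by −0.40 ± 0.23 (adjusted p = 0.669), Gys2 by 0.28 ± 0.21, Pck1 by −0.19 ± 0.37, Acly by −0.13 ± 0.21, Fbp1 by 0.09 ± 0.28 and Pdk4 by 0.01 ± 0.19. G6pc had a value under 35 in 4 of 6 vehicle animals and in 0 of 6 treated animals, so that only a bound of its treated level was measured. None of the 10 lists passed (lowest adjusted p = 0.581), and no list held a called gene, over all genes or adjusted over the list alone. The median half-width of the 95% intervals was 0.406 log2 units. The median Ct over the tested genes was later in PPARα-null 2,4-DNT animals than in PPARα-null vehicle animals, by 0.309 cycles (exact permutation test, p = 0.0368). With the median of the genes as the reference, which shifts every log2 fold change here by 0.38, 6 lists turned positive and passed. Relative to B2m no list passed with camera and an estimated correlation (lowest adjusted p = 0.972) or with exact permutation (0.238).

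Whether the effect of 2,4-DNT differed between the genotypes was tested by the interaction. No gene passed (limma, lowest adjusted p = 0.303), 4 genes had an unadjusted p under 0.05, and a permutation test called 0. Pdpr had the largest positive difference, with 1.53 ± 0.50 (SE, adjusted p = 0.303), so the fall seen in wild-type mice was not shown to differ from the change in PPARα-null mice. G6pdx differed by 0.72 ± 0.47 (adjusted p = 0.767) and Pklr by −0.88 ± 0.32 (adjusted p = 0.303). The values of Fbp1, Gys2, Pck1, Acly and Pdk4 were 0.69 ± 0.40, 0.48 ± 0.30, 0.20 ± 0.53, −0.11 ± 0.29 and −0.25 ± 0.27, and Pck1 turned to −0.33 ± 0.21 without the wild-type 2,4-DNT animal A red. G6pc gave 0.79 ± 0.73, with animals at the ceiling in every group. None of the 10 lists passed (lowest adjusted p = 0.552), and none held a called gene by either count. The median half-width of the 95% intervals was 0.575.

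The third comparison set PPARα-null against wild-type mice on vehicle. Here 7 genes were higher and 1 lower in PPARα-null liver, relative to B2m. Pklr was higher by 0.86 ± 0.23 (log2, SE, 1.82-fold, adjusted p = 0.0232), with −ΔCt of 1.46 ± 0.48 in wild-type and 2.32 ± 0.51 in PPARα-null animals (SD, n = 6). Pgm3, a mutase of amino-sugar synthesis, was higher by 0.67 ± 0.14 (adjusted p = 0.00844) and Gsk3b, a kinase that acts on glycogen synthase, by 0.67 ± 0.19 (adjusted p = 0.0451). Fh1 (fumarase), Phkg2 (the catalytic subunit of liver phosphorylase kinase), Gpi1 (glucose-6-phosphate isomerase) and Rbks (ribokinase) were higher by 0.54 ± 0.14, 0.47 ± 0.15, 0.44 ± 0.13 and 0.36 ± 0.12, with adjusted p values of 0.0232 to 0.0498. G6pc was lower by a log2 fold change of −1.64 ± 0.52 (adjusted p = 0.0488), close to the ceiling, with a value under 35 in 5 wild-type and 4 PPARα-null animals. With a ceiling of 40 it differed by −2.33 ± 0.84 and no longer passed (adjusted p = 0.0760). For each of these 8 genes all 6 PPARα-null animals lay on the same side of the wild-type mean, which also held for genes that did not pass, such as Pdk4. All 6 PPARα-null animals lay above all 6 wild-type animals for 3 of the 8, Gpi1, Pgm3 and Rbks, where chance gives 0.175 genes of 81. Within prefixes A, A2, B and B2, with 1 or 2 animals per group each, the difference did not keep its sign for G6pc (−1.73, −2.91, −3.20 and 0.60), Phkg2 (0.62, −0.21, 0.92 and 0.28) and Pklr (−0.04, 0.06, 1.28 and 1.29), and kept it for the other 5 genes.

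Most of the plate leaned the same way on vehicle: 69 of 81 genes had a positive log2 fold change, with a median of 0.272, and 20 had an unadjusted p under 0.05. In raw Ct the median over the tested genes was earlier in PPARα-null animals by only 0.0696 cycles (exact permutation test, p = 0.732), and B2m was later by 0.0976 cycles. The directional test passed for 5 lists relative to B2m. None of the 5 directional results held with camera and an estimated correlation (adjusted p = 0.924 each), with the median of the genes as the reference (0.415 or more), with the prefix as a block (0.0576 each) or with exact permutation (0.189 or more). The mixed test passed for glycolysis alone (adjusted p = 0.0149, with the prefix as a block 0.0214, with the median of the genes as the reference 0.328). In the other 4 comparisons the mixed test passed for no list relative to B2m (lowest adjusted p = 0.983), and with the median of the genes as the reference for glycolysis and the citric acid cycle with 2,4-DNT in PPARα-null mice (adjusted p = 0.0336 each). In glycolysis 3 of 20 members were higher (4 adjusted over the list alone, adjusted p = 0.0401), namely Pklr, Gpi1 and Pgm3. Pgm3, described above as a mutase of amino-sugar synthesis, counts here and in glycogen breakdown because the preset lists hold it. Glycogen synthesis had 1 of 6 higher, Gsk3b (1 adjusted over the list alone; adjusted p = 0.0401), glycogen breakdown 2 of 10, Pgm3 and Phkg2 (2 adjusted over the list alone; adjusted p = 0.0401), and the pentose phosphate pathway 1 of 10, Rbks (3 adjusted over the list alone; adjusted p = 0.0413). Liver-type isozymes held 2 higher genes, Pklr and Phkg2, and 1 lower, G6pc, of 9 (3 adjusted over the list alone; adjusted p = 0.0413), with a median of 0.35 and a mean of 0.11. The pyruvate dehydrogenase list (adjusted p = 0.0752), the citric acid cycle (0.189), isozymes of other tissues (0.205), testis isozymes (0.189) and gluconeogenesis (0.876) did not pass. They held 0, 1, 0, 0 and 1 called genes, and the same numbers adjusted over the list alone. The preset genes Pdk4, Gys2, Pck1, Acly, Fbp1 and G6pdx differed by 0.34 ± 0.19, −0.06 ± 0.21, 0.17 ± 0.37, −0.24 ± 0.21, 0.06 ± 0.28 and 0.12 ± 0.33, and none passed. All 8 calls ended under each of 6 other references. The log2 fold changes of the 7 higher genes shrank under all 6, Rbks to −0.02 relative to Gusb, while that of G6pc lay between −2.02 and −1.80. The count was 1 without the wild-type vehicle animal B blue or B none or the PPARα-null vehicle animal B none. It was 3 with the prefix as a block and 3 with the colour as a block. When 4 housekeeping genes were tested too it was 4, and when only the 12 vehicle animals entered the fit it was 0.

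**Figure D3:**
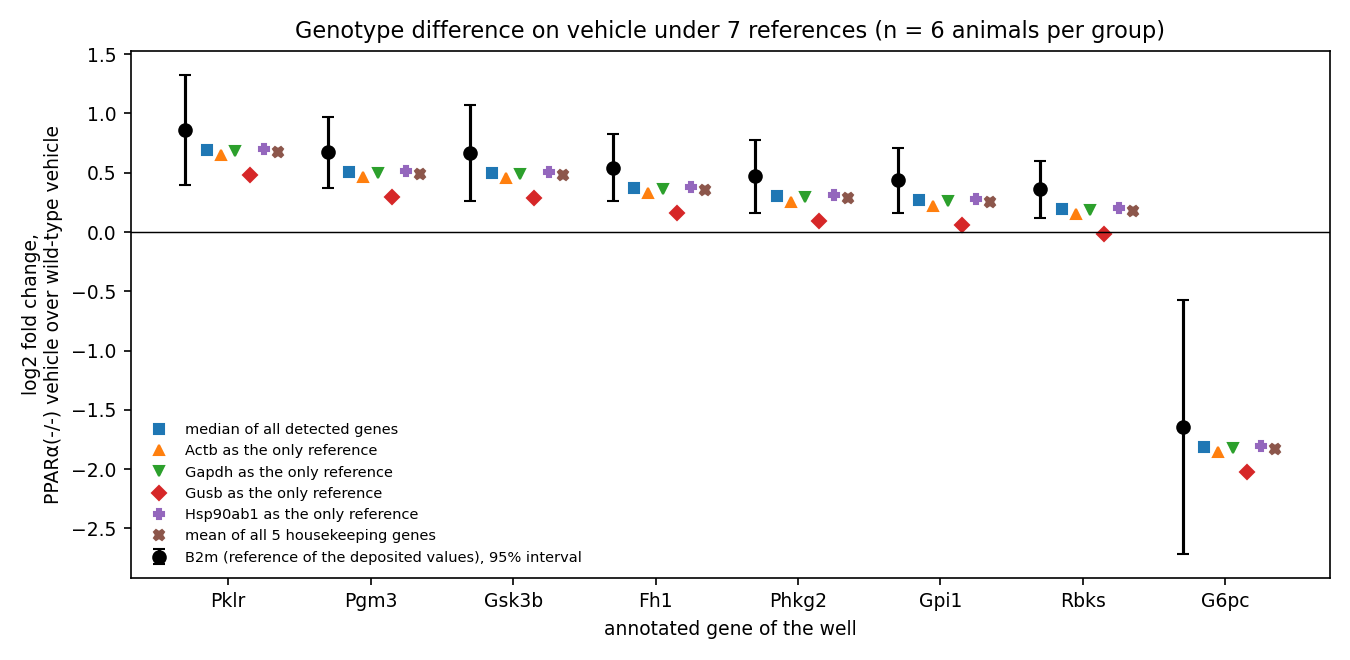
Log2 fold change of PPARα-null over wild-type mice on vehicle (vertical axis) for the 8 genes past the threshold, relative to B2m (black, with the 95% interval from 6 animals per group) and relative to 6 other references (coloured symbols, no interval drawn). Values relative to B2m run from 0.86 for Pklr to 0.36 for Rbks and −1.64 for G6pc, and Rbks lies at −0.02 relative to Gusb.

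The last comparison set the genotypes against each other on 2,4-DNT. Pdpr was higher in PPARα-null than in wild-type animals by 1.97 ± 0.35 (log2, SE), or 3.91-fold (limma, adjusted p = 0.000854), with all 6 PPARα-null animals above all 6 wild-type animals. No other gene passed, and 6 had an unadjusted p under 0.05. G6pdx differed by 0.85 ± 0.33 (adjusted p = 0.468), Fbp1 by 0.74 ± 0.28 (adjusted p = 0.468), Gys2 by 0.42 ± 0.21, Pck1 by 0.37 ± 0.37 (−0.16 ± 0.15 without the wild-type animal A red), Pdk4 by 0.09 ± 0.19, Pklr by −0.02 ± 0.23, Acly by −0.35 ± 0.21 and G6pc by −0.85 ± 0.52. G6pc was at the ceiling in 2 wild-type and 6 PPARα-null animals, so this value bounds the difference in neither direction. None of the 10 lists passed (lowest adjusted p = 0.633), and the pyruvate dehydrogenase list alone held a called gene, 1 by either count. Within prefixes A, A2, B and B2 the Pdpr difference was 2.42, 1.42, 2.11 and 1.96. The median Ct was later in PPARα-null animals, by 0.413 cycles (exact permutation test, p = 0.0130). With the median of the genes as the reference 3 lists passed with positive means, pyruvate dehydrogenase, the pentose phosphate pathway and glycogen synthesis (adjusted p = 0.0345 each). Relative to B2m no list passed with camera and an estimated correlation (lowest adjusted p = 0.915) or with exact permutation (0.606). This comparison shares the wild-type 2,4-DNT animals with the first, so the 2 Pdpr calls are not independent.

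The housekeeping genes were tested on raw Ct. None of Actb, B2m, Gapdh, Gusb and Hsp90ab1 passed in any comparison, and the lowest adjusted p was 0.154 with limma and 0.0974 with the exact permutation test. B2m itself was later in PPARα-null than in wild-type animals on 2,4-DNT, with −Ct lower by a difference of −0.24 ± 0.11 (SE, adjusted p = 0.154). Hsp90ab1 had the widest spread, with a standard error of 0.38, and was earlier by 0.71 with 2,4-DNT in wild-type mice (adjusted p = 0.187).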

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

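The tests of explanations in this part were written down after the results they measure had been seen. In 11 of 92 sets of 6 animals, 1 animal lay further from the others than Dixon's 95% limit allows, where chance gives about 4.6.

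The wild-type vehicle animal B blue stood apart in 3 measures. Its Pdpr −ΔCt was 0.66, against −1.99 to −1.47 in the other 5 animals. Its Rbks −ΔCt was −2.39, against −1.93 to −1.70, and its Actb Ct 25.6, against 24.4 to 24.8. The wild-type 2,4-DNT animal B2 blue had a reverse transcription control at 18.6 cycles, against 21.7 to 21.9, and an Hsp90ab1 Ct of 21.2, against 19.5 to 20.0. In the wild-type 2,4-DNT group, Pck1 was at −1.51 in animal A red, against 1.53 to 1.82, and Gsk3b at −0.16 in animal B2 red, against 0.48 to 0.77. Among PPARα-null animals, Gys2 was at −4.72 in vehicle animal B none, against −5.88 to −5.64. Actb was at 25.1 cycles in vehicle animal B blue, against 24.5 to 24.6. Hsp90ab1 was at 22.5 cycles in 2,4-DNT animal B none, against 19.9 to 20.9, and the reverse transcription control at 21.9 in 2,4-DNT animal A2 none, against 21.7.

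The fall of Pdpr with 2,4-DNT in wild-type mice was set against 3 technical explanations and chance. All 6 other references and all 24 fits without 1 animal kept the call, with 95% intervals of the log2 fold change below 0. Only the fits without 1 of the 12 wild-type animals can move this log2 fold change. The other fits change only the shared spread. The tables thus argue against B2m or a single animal as the whole cause. The colour of the column is uneven between the groups, and as a block it ended the call (adjusted p = 0.0620), but the log2 fold change went only from −1.59 ± 0.35 (SE) to −1.50 ± 0.38, so the tables argue against colour as the whole cause too. Of 100 splits of the 12 wild-type animals, the real one included, 3 gave at least the 2 calls of the real one. The highest other split had 2. This share is under 0.05, but 100 splits are too few to exclude chance for the count. An effect of 2,4-DNT on the RNA read by this well may remain as a hypothesis, and it stays open what that RNA is.

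For the fall of G6pdx, at −1.23 ± 0.33 (log2, SE), 3 of the 6 other references ended the call and leaving out 1 animal ended it in 13 of 24 cases (highest adjusted p = 0.170, without the wild-type vehicle animal B blue). The 95% interval of the log2 fold change, which is not adjusted over the genes, stayed below 0 under all 6 other references (−1.74 to −1.20) and in all 24 fits without 1 animal (−1.41 to −1.08). Fits without a PPARα-null animal change only the shared spread here. The intervals argue against B2m or a single animal as the whole cause of the measured fall, though the call depended on both. With the colour as a block it was −1.19 ± 0.34 (adjusted p = 0.0843), which argues against colour as the whole cause too. An effect of 2,4-DNT may remain as a hypothesis for this well, but the call depends on the setting and what the well reads stays open.

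The 8 genotype calls on vehicle were set against the reference gene, single animals and chance. For the 7 higher genes the reference stays open, since 0 of 7 had a 95% interval above 0 under all 6 other references, 5 had one with the median of the genes, and none had one with Gusb or Hsp90ab1, whose errors were larger than with B2m. For G6pc, close to the ceiling, the call ended with a ceiling of 40 (−2.33 ± 0.84, adjusted p = 0.0760) and with every other reference, but the interval stayed below 0 under all 6 references and the log2 fold change moved away from 0 (−1.64 ± 0.52 to between −2.02 and −1.80), so the tables argue against B2m as the whole cause. Leaving out 1 animal kept as few as 1 of the 8 calls, without the wild-type vehicle animal B blue or B none or the PPARα-null vehicle animal B none. The call ended in 0 of 24 fits for Pgm3, and in 3 for Fh1 up to 19 for Rbks among the others. All 8 intervals, which are not adjusted over the genes, stayed on their side of 0 in all 24 fits. Fits without a 2,4-DNT animal change only the shared spread in this comparison. The intervals argue against a single animal as the whole cause of the differences, but the calls depended on single animals. The wild-type vehicle animals B blue and B none also had the latest reverse transcription controls of the 24 animals, at 22.6 and 22.1 cycles, and the latest median Ct of their group. Fits that leave out 1 animal do not decide whether these 2 together shaped the differences. The fit without both doubted animals does not decide it either, since it left out B blue but kept B none. Of 100 splits of the 12 vehicle animals, the real one included, 4 gave 8 calls or more, so chance was excluded at this level for the count, and the highest other gave 27, several times the real count. That may come from a structure of the samples or from B2m, which all genes share, and with the median of the genes as the reference the same split gave 2.

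For 2,4-DNT in PPARα-null mice and for the interaction the real count was 0, so that all 100 of 100 splits or draws give as many by design and this test decides nothing. The highest others gave 24 and 4, and the split with 24 gave 0 with the median of the genes as the reference. For the genotypes on 2,4-DNT, with 1 call, 5 of 100 splits gave as many, the real one included. The highest other gave 1, and chance was not excluded for the count. With a real count of 1 the test asks only whether a split gives any call. It does not weigh the size of the Pdpr difference, so it does not decide on chance for that gene.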

How the results depend on the processing

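The blocks, the fit without both doubted animals, the list test without the wild-type 2,4-DNT animal A red and the fit with housekeeping genes tested too were chosen after seeing the data. No paired analysis was possible because the columns carry no replicate numbers and up to 2 animals of a group share a prefix, so that no animal is tied to a single other. The planned block on replicate numbers was therefore not run, and the prefix, which occurs in every group, was run as a block instead. For G6pc with late values missing and for Fbp1 and G6pc under the filter at a mean Ct of 30 no value could be had. For 2,4-DNT in wild-type mice the count of 2 became 1 with the median of the genes, Gapdh or Gusb as the reference, with a ceiling of 40, with the prefix as a block and without both doubted animals. It became 3 with Hsp90ab1 as the reference. It became 0 with the colour as a block and with exact permutation, which can pass only if 4 genes reach its smallest p. Leaving out 1 animal gave 1 to 3. For PPARα-null mice and for the interaction all counts stayed at 0, leave-one-out included. For the genotype on vehicle the count of 8 (7 higher, 1 lower) became 9 with a ceiling of 40 (9 higher, 0 lower, the G6pc call lost), 9 with the filter at a mean Ct of 30, 10 with a trended robust spread and 11 with no filter. It became 0 with the median, Actb, Gapdh, Gusb, Hsp90ab1 or the mean of all 5 housekeeping genes, with only the 2 groups compared and with exact permutation. It became 4 with a fold of 1.5, 4 with late values missing, 3 with the prefix and 3 with the colour as a block, 1 without both doubted animals and 4 with housekeeping genes tested too. Leaving out 1 animal gave 1 to 14, with 1 without the wild-type vehicle animal B blue or B none or the PPARα-null vehicle animal B none, and 14 without the PPARα-null vehicle animal B blue. For the genotype on 2,4-DNT the count of 1 became 0 with exact permutation alone, where a lone gene cannot go below an adjusted p of 0.175. Causes were not tested, apart from these limits of the exact test.

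Pdpr in wild-type mice ran from −1.72 to −1.19 on leaving out 1 animal (adjusted p 0.00791 to 0.0406). The smallest fall was without the vehicle animal B blue, and it was −1.18 without both doubted animals. Between genotypes on 2,4-DNT it ran from 1.85 to 2.08. Relative to Gusb, Rbks reversed to −0.0190 for the genotype on vehicle (adjusted p = 0.989). The median of the genes as the reference shifts every log2 fold change by 0.38 for 2,4-DNT in PPARα-null mice, −0.17 for the genotype on vehicle, 0.17 for the genotype on 2,4-DNT and 0.03 for 2,4-DNT in wild-type mice. With it, list means for 2,4-DNT in PPARα-null mice reversed to 0.237 for glycolysis, 0.256 for pyruvate dehydrogenase, 0.300 for the citric acid cycle, 0.246 for the pentose phosphate pathway, 0.305 for glycogen synthesis and 0.248 for glycogen breakdown, with adjusted p of 0.0201 to 0.0401. Relative to B2m none of these lists passed with camera and an estimated correlation (adjusted p = 0.972 each) or with exact permutation (0.722 each). For liver-type isozymes on vehicle, with a mean of 0.107, the test pointed down under camera (adjusted p = 0.924) and up in fry. Without the wild-type 2,4-DNT animal A red, the sign of Pck1 reversed for 2,4-DNT in wild-type mice (0.13), for the interaction (−0.33) and for the genotype on 2,4-DNT (−0.16), and none passed. The 5 lists past the threshold on vehicle passed the directional test in none of the 4 other settings, which were the median of the genes as the reference, permutation, camera and the prefix as a block. Of 615 alternative values of results that passed no threshold, 48 had the other sign. Where both groups stand at the ceiling no difference can be seen.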

Other observations

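The tests in this part were chosen after the levels had been seen, while the gene lists they use were fixed before. The well annotated Pcx, pyruvate carboxylase, which makes oxaloacetate from pyruvate, was singled out after its values were seen. With 2,4-DNT it had a log2 fold change of −0.93 ± 0.37 (SE, adjusted p = 0.320) in wild-type and of −0.95 ± 0.37 (SE, adjusted p = 0.560) in PPARα-null mice. Neither passed the threshold. In both genotypes all 6 treated animals lay below the vehicle mean, which was not particular to Pcx, since it also held for G6pc in both. In the PPARα-null vehicle group G6pdx lay at 2.08 and 2.10 in the animals B blue and B2 blue and between 3.05 and 3.89 in the other 4.

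The late Ct of wells annotated as liver-type isozymes may come from names displaced against the wells. When every name was read a fixed number of wells later, the mean Ct of isozymes of other tissues minus that of liver-type isozymes was −1.26 at 0 wells and 6.04 at 2 wells, the highest of 13 offsets from −6 to 6 (permutation of Ct over the wells, p = 0.0002, best offset taken in each permutation). Low RNA input would delay all wells, and 3 gene wells had a mean Ct below 20. That limit was set after the values were seen, and no level at normal input was at hand, so this count does not decide on low input. A delay shared by all wells would leave the sign of the difference between the lists as it was. The same animals gave −6.16 in rows A to D and 6.53 in rows E to G. This argues against low input alone as the cause of the reversed order in rows A to D. Treatment or genotype are argued against because the difference was −1.10 in wild-type vehicle animals too. In plate rows A to D the difference went from −6.16 at 0 wells to 9.51 at 2 wells, while in rows E to G it went from 6.53 to 0.58, so any displacement may hold for part of the plate alone. Other layouts remain open, since no assay list of the supplier was used here.

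Read 2 wells later, the name at the well annotated G6pdx would be G6pc, that at Pcx would be Pck1 and that at Pdpr Pdk4. Pdpr lies in row E, and over rows E to G together the displaced reading separated the lists less well. In row E itself, Pfkl went from 31.3 to 21.6 cycles and Pgam2 from 31.1 to 35, as a displacement would give. Pgk2 went the other way, from 35 to 23.1. Of the wells called for the genotype on vehicle, those in rows B and C would be Fbp1 for Fh1, Fbp2 for G6pc, Gbe1 for Gpi1 and Gpi1 for Gsk3b. Those in rows E and F would be Pgm1 for Pgm3, Phkb for Phkg2, Phkg1 for Pklr and Pygl for Rbks. Whether gluconeogenic genes fell together under that reading was tested with fry, and the tests leave it open. The 7 wells had a mean log2 fold change of −0.41 in wild-type mice (4 of 7 negative, adjusted p = 0.158) and of −0.36 in PPARα-null mice (6 of 7 negative, adjusted p = 0.110). These p values were adjusted over the 2 genotypes, those at the named wells over 10 lists. Unadjusted, fry gave 0.158 and 0.0548 here, against 0.0177 and 0.106 at the named wells. With the median of the genes as the reference neither passed (adjusted p = 0.412 for both) and the direction in PPARα-null mice turned positive. Until the layout is known, the gene names of wells in this series, those of Pdpr and G6pdx included, may need checking. The same holds for the results of the gene lists, which group the wells by these names.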
